A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

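The samples are chromatin immunoprecipitations from budding yeast (Saccharomyces cerevisiae) strain MDY510, which per the labels carries a Myc-tagged histone H3 made constitutively and a Flag-tagged H3 made from a galactose-induced gene. Per the labels' protocols, cells grown with 2% raffinose were arrested in G1 for 3 h with alpha factor (4 µg/mL) and moved to 2% galactose while arrested. Chromatin taken 60, 90, 120 or 150 min later was precipitated with an anti-Myc or an anti-Flag antibody, up to 75 ng of DNA was amplified linearly through RNA, and 3 µg of the amplified RNA was labelled. Per the labels, the Myc precipitate carried Cy5 and the Flag precipitate carried Cy3 on each of the 7 arrays, so no dye swap balances a dye effect. The ratio of Flag to Myc at a probe ranks loci by the share of Flag H3 among the tagged H3 there. No untagged or input array was used here.

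The deposited scanner files hold spot intensity values from Agilent Feature Extraction 8.5.1.1, per the file headers. Per the file headers, each processed intensity was background-subtracted with a fitted surface and multiplied by 1 linear dye factor per channel, with no lowess step. The deposited series table holds log2 ratios of Myc over Flag, and it matched the log2 ratio of the processed signals of the same array within 5e-06 at every probe compared. Its columns were not centred, with medians of 0.5727 (60 min), 0.4491 and 0.3361 (90 min, sets 2 and 5), 0.3371 and 0.3039 (120 min) and 0.4165 and 0.479 (150 min). Other columns used from the deposited files are the scanner's 0 or 1 flags for outlier spots, saturation and signal well above background. The genome build of the probe coordinates is not given in the sources used here.

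The value used throughout is log2(Flag/Myc), the opposite direction to the deposited table, computed from the processed signals and centred on each array's median over 41418 non-control probes. Spots with an outlier flag in either channel were set to missing. They made up 33.9% of spots on the 120 min set 2 array and between 1.11% and 9.28% on the others, and 1 damaged line on the 120 min set 2 array was also set to missing. Saturated spots were kept; no array had more than 7 of them in a channel.

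Signal over background sets what the arrays can resolve. The median Flag signal ran from 175.9 (90 min, set 5) to 2241.7 (120 min, set 2), and 78.2% of Flag spots were well above background on the first of these, against 88.4% to 99.8% on the other 6 arrays. For Myc, 92.2% to 99.8% of spots were well above background. Arrays fell into 3 scans. Scan 1 held the 120 min set 2 array, scan 2 held 90 min set 2, 120 min set 5 and both 150 min arrays, and scan 3 held the 60 min array and 90 min set 5.

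Probe positions were those in the files, about 265 bp apart per the labels. The files name the nearest gene of each probe with a distance. Their words for the position in the gene held for genes on the Watson strand, where 99.9% of probes in coding bodies read as inside, but not on the Crick strand, where 1.49% did. Gene ends were therefore rebuilt from the distances. The left end of a gene was fixed by them in 6555 of 6593 open reading frames, and the right end was bracketed by neighbouring probes (median bracket 301 bp). Names came from a RefSeq gene table (assembly R64, names only); 5927 open reading frames matched a protein-coding gene, and 5643 genes with a bracket of at most 600 bp were kept, 2828 on the Watson and 2815 on the Crick strand. A promoter value is the mean of probes centred within 500 bp upstream of the coding start, and a body value the mean of probes between coding start and stop. Neighbouring genes can share promoter probes. Location classes used probes within 500 bp of 275 tRNA genes, 72 snoRNA genes, 16 centromeres or 422 Ty elements and LTRs, and within 10 kb of a chromosome end. A class with fewer than 10 probes was given values and no test.

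The groups were 60 min (n = 1), 90, 120 and 150 min (n = 2 each), and the replicate number is the set number, 2 or 5. Models were fitted with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with a coefficient per time point, 3 residual degrees of freedom and Benjamini-Hochberg adjustment over all features tested, at a threshold of 0.05. The mean ratio is the equal-weight mean of the 4 time points tested against 0, the array median. The time change is 150 min minus 90 min, and a linear slope per 30 min was fitted with 5 residual degrees of freedom. The single 60 min array adds no residual, so its own error does not enter the SE. Per-array medians were tested with an exact two-sided sign-flip permutation test over 7 arrays, whose smallest p is 0.015625. The 16 gene lists were tested with limma's camera at a preset correlation of 0.01 on genes measured on every array, with an estimated correlation and fry as alternatives. The ribosomal protein, proteasome, PAU and COS lists took every gene whose symbol had a set form. Family membership was not checked, and RPP1 and COS111 entered the ribosomal protein and COS lists by symbol alone. Nothing in the labels says that sets came from separate cultures, so p-values measure only the spread between these samples, which may be technical, and the number of arrays limits the precision.

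Groups, tests, gene lists, most alternative settings and the rule for named genes were fixed before the data were examined. The rule takes genes with a standard symbol and at least 1 probe well above background in both channels on all arrays. It takes the 8 highest and 8 lowest promoters and the 6 highest and 6 lowest bodies that pass with 1 sign on every measured array, and the 6 largest rises and falls with time that pass with 1 direction in both sets (or 3 each as values if none pass). It adds the 4 highest and 4 lowest promoter minus body differences, up to 4 passing members of each list by size (2 as values if none pass), and, whatever their values, GAL1, GAL7, GAL10, HHT1, HHT2, HHF1, HHF2, BAR1, FUS1 and the silent cassette genes. Not all genes taken by the rule are reported here. Alternatives covered background correction (normexp, offset 50), dye normalization, loess, centring on coding bodies, a filter on dim probes, kept outlier spots, the deposited table, set as a block, scan as a block, each array or set left out, eBayes options and other distances. Added after the data were seen were Watson genes alone, scan as fixed terms, the arrays of scan 2 alone, those without scan 3, and the class of replication origins.

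The code was tested on simulated data drawn with the fitted spread of each feature, with 200 features changed. For the mean ratio of 5503 promoters, a log2 size of 1 was recovered in 96.5% and a size of 0.5 in 1.5%; for 5221 bodies a size of 0.5 was recovered in 98%. For the change from 90 to 150 min, a size of 1 was recovered in 93% of changed bodies but in 0% of 200 changed promoters, and a size of 2 in 92.5% of promoters. For 37235 probes a time change of 1 was recovered in 0% and of 2 in 80.5%. With no simulated change, the time test made 0 calls among promoters, 0 among bodies and 3 among probes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.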

Results

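Newly made histone H3 was followed in yeast cells held in G1, where DNA is not replicated, so that its entry into chromatin could be mapped apart from replication. The data are 7 arrays from 4 times after galactose was added: 60 min (1 array, set 5) and 90, 120 and 150 min (2 arrays each, sets 2 and 5). Each array set Flag-tagged H3, made after galactose, against Myc-tagged H3, present throughout, at probes across the genome. Values are log2(Flag/Myc) relative to the array median, so a positive value marks a locus where new H3 is a larger share of the tagged H3 than at the typical probe. Here and below, new H3 means Flag H3. Myc H3 is made constitutively, so it is not purely old H3 and can include H3 made after galactose. A high share can come from much Flag or little Myc H3, and the values say nothing about absolute amounts. This direction is the inverse of the deposited ratio of Myc over Flag. Errors are SE of the mean of the 4 time points unless stated, from all 7 arrays where no other number is given.

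The 7 maps resembled each other. Across probes, which are not independent replicates, the correlation between arrays ran from 0.7931 to 0.9697 over 21 pairs. It was 0.8761 to 0.9631 for arrays of the same time. Set 2 arrays of different times correlated at 0.954 to 0.9697, above the same-time pairs at 90 min (0.8761) and 120 min (0.9054). Set 5 arrays of different times correlated at 0.7931 to 0.9179. The 60 min array stood furthest from the rest, with r between 0.7931 and 0.8913. Of 37235 probes tested, 15440 lay above and 15262 below the array median in the mean over time (limma). Without the 120 min set 5 array, 24719 probes could be tested and 9926 lay above and 10449 below. Centring on coding bodies in place of all probes raised values by 0.50 on the log2 scale and put 70.05% of calls above, against 50.29%.

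Promoters had a higher share of new H3 than the typical probe, and the highest values were at promoters of core histone genes. Genes named here and below as highest, lowest or most changed are those well above background in both channels on all arrays. The highest value was at the promoter of HTB1, which encodes histone H2B (YDR224C, chromosome 4, probes from 915014 to 915262), at 5.23 ± 0.15 or 37.5-fold. Next came the region shared by HHT2 and HHF2, the divergent genes for H3 and H4 (chromosome 14, 576207 to 576577), at 4.87 ± 0.11 or 29.3-fold, and HTA1, for H2A, at 4.61 ± 0.28. Promoters of SPO73 (a sporulation gene, 4.41 ± 0.11), CMC4 (a mitochondrial protein, 4.29 ± 0.12), HEM12 (heme synthesis, 4.29 ± 0.11) and NRT1 (a nicotinamide riboside transporter, 4.28 ± 0.11) followed. Each was above the median on all 7 arrays with a limma adjusted p of 2.13e-05 or less. In all, 4474 of 5503 promoters lay above the array median and 187 below, 2787 of them more than 2-fold above.

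The lowest promoters included genes near chromosome ends and at mating-type loci. PAU8, a seripauperin gene, was at -1.67 ± 0.11 (6 arrays measured), and AAD15, a putative aryl-alcohol dehydrogenase gene, at -1.60 ± 0.09. The promoter of MATALPHA2 was at -1.51 ± 0.11 (6 arrays measured). It is read by 1 probe, which also lies in the body of MATALPHA1. As background, alpha factor arrests cells of mating type a, which carry alpha sequence only at the silent HML locus. The promoter shared by the silent genes HMRA1 and HMRA2 was at -1.11 ± 0.15. Whether probes at HML and HMR also read the MAT locus could not be tested, here or for the values of these loci below. ADY3 (spore formation, -1.29 ± 0.09), VBA3 (a vacuolar permease, -1.21 ± 0.16, 5 arrays measured) and SRT1 (polyprenol synthesis, -1.18 ± 0.10) complete the 8 lowest. All had a limma adjusted p of 0.00257 or less and were below the median on every array measured.

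Among the fixed lists, all 11 galactose-regulon promoters lay above the median (median 2.20), with GAL10 at 2.91 ± 0.10, GCY1 at 2.59 ± 0.11, GAL7 at 2.43 ± 0.19, FUR4 at 2.43 ± 0.18 and GAL1 at 2.20 ± 0.10. All 16 promoters of glycolysis and ethanol genes did so too (median 2.40; PDC1 3.46 ± 0.13, ADH1 3.37 ± 0.15, FBA1 3.06 ± 0.17), as did 11 of 11 histone gene promoters (median 1.97) and 28 of 28 of pheromone-induced and mating genes (median 1.57; SST2 2.31 ± 0.23, ASG7 2.09 ± 0.13, MFA2 2.07 ± 0.21, BAR1 2.05 ± 0.10). Of 135 promoters of the ribosomal protein list all but 7, RPP1 among the exceptions, lay above and 0 below (median 1.38, RPS3 3.37 ± 0.12). RPS4A had a mean of 3.499, but its values ran from 0.218 to 8.638 between arrays. For general stress genes 16 of 17 lay above (XBP1 3.76 ± 0.29, DDR2 2.80 ± 0.14), for glucose-repressed carbon genes 11 of 12 (JEN1 3.34 ± 0.11, SUC2 2.36 ± 0.26), and for phosphate-starvation genes 7 above and 1 below of 8 (PHO84 3.53 ± 0.18, PHO89 2.57 ± 0.12). The 2 promoters of the COS list, COS9 (0.54 ± 0.11) and COS111 (2.51), were above. Of 23 G1/S promoters 21 lay above and 1 below (CLN2 2.37 ± 0.10, HCM1 2.04 ± 0.19), of 10 G2/M promoters 8 and 1 (MYO1 2.86 ± 0.18), of 18 ribosome biogenesis promoters 12 and 1 (CBF5 1.82 ± 0.20), and of 32 proteasome promoters 24 and 1 (PRE8 3.16 ± 0.48, PUP2 1.73 ± 0.13). Not well above background on all arrays, and so not among these examples, were higher promoters in the last and the ribosomal protein list, PRE7 (4.28 ± 0.10) and RPL15B (4.49 ± 0.21, 6 arrays measured). Promoters of PDC1, MFA2, BAR1, JEN1, SUC2, PHO84, PHO89 and PRE8 were measured on 6 arrays. Among genes fixed in advance, the promoter of the fusion gene FUS1 was at 1.33 ± 0.09 and that shared by HHT1 and HHF1, the other genes for H3 and H4, at 1.70 ± 0.44, neither well above background on all arrays. The HHT1 and HHF1 value did not pass without the 60 min array (1.02), in set 2 alone (0.14) or in scan 2 alone (0.57). Among the 11 histone promoters a value is shared by HHT1 and HHF1, by HHT2 and HHF2, and by HTA2 and HTB2. Each shared value is counted for both genes.

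Against other promoters rather than the array median, 3 lists stood lower by camera, 1 of them (silent cassettes) through a single shared value, and none passed as higher. Leaving out an array changed this for glycolysis genes, which passed as higher without 120 min set 2 (adjusted p = 0.0248), 120 min set 5 (0.0356) or 150 min set 5 (0.0486), and for galactose and histone genes, which did so without 150 min set 5 (0.0486 for both). With an estimated correlation and all arrays the adjusted p = 0.715 for these 3 lists. The histone list counts each shared promoter value for both genes that share it. Promoters of meiosis and sporulation genes had a median of 0.37 against 1.01 for other genes, with 8 above and 4 below among 19 (adjusted p = 0.00386), or 15 above and 0 below with arrays centred on coding bodies (median 0.85); IME2, a meiotic kinase gene, was at 2.79 ± 0.09 all the same. The 6 PAU promoters had a median of -0.32, with 1 above (PAU7, 1.27 ± 0.10) and 3 below (adjusted p = 0.000372), and this median was 0.17 with arrays centred on coding bodies. With only probes well above background the PAU list did not pass (adjusted p = 0.0969). The 4 silent cassette promoters split: HMRA1 and HMRA2 shared 1 value below the median, while HMLALPHA1 and HMLALPHA2 shared 1 above (1.54 ± 0.38, 6 arrays measured, not well above background on all arrays). The list's adjusted p of 1.49e-05 rests on the HMR pair alone, because the other was not measured on every array. It counts 1 shared value as 2 genes, so it is not a test of the list. For each of the 3 lists the adjusted p = 0.212 with an estimated correlation. Counts adjusted over the list alone were the same as those given for every promoter list. The phosphate-starvation list had a median above that of other genes but a camera direction downward (adjusted p = 0.836), over 4 genes measured on every array, and with a 250 bp window it passed downward (0.00424).

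Coding bodies had a lower share of new H3 than the typical probe, except at a minority of genes. These included 9 of 11 galactose-regulon genes and 22 of 25 pheromone-induced and mating genes. The highest bodies were TOS8 (a homeobox protein, 4.34 ± 0.09, 6 arrays measured), AHP1 (a thiol peroxidase, 4.29 ± 0.07), GAL10 (4.21 ± 0.06, 18.6-fold), SPO24 (4.19 ± 0.11, 6 arrays measured), FAR1 (which inhibits the cyclin-dependent kinase on pheromone treatment, 4.16 ± 0.09, 17.8-fold) and SRD1 (4.11 ± 0.09). The lowest were PHO12 (an acid phosphatase, -1.74 ± 0.08), HMLALPHA1 (-1.70 ± 0.06), DAN4 (a cell wall protein, -1.51 ± 0.06), MATALPHA1 (-1.51 ± 0.07, 6 arrays measured), BSC1 (-1.50 ± 0.06) and FMP42 (a mitochondrial protein, -1.45 ± 0.09). Each passed limma with an adjusted p of 1.72e-06 or less and 1 sign on every array measured. Of 5221 bodies, 1703 lay above the array median and 2787 below, with a median of -0.25. Centred on coding bodies the split was 2827 above and 1352 below, so the sign of a body near 0 depends on the centring.

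By list, 22 of 25 bodies of pheromone-induced and mating genes lay above the median and 1 below (median 2.53; SST2 3.05 ± 0.07, AGA1 3.03 ± 0.09, PRM4 2.93 ± 0.08, FUS1 2.53 ± 0.08). BAR1 was at 1.92 ± 0.41 and not well above background on all arrays; its mean was 1.17 without the 60 min array and 0.045 in set 2 alone, where it did not pass. Of 16 glycolysis and ethanol genes, 15 were above (median 2.15; TDH3 3.26 ± 0.06, PDC1 3.12 ± 0.07, PGK1 2.70 ± 0.08), and of 11 galactose-regulon genes, 9 above and 1 below (median 1.95; GAL2 3.76 ± 0.08, GAL1 3.56 ± 0.06, GAL7 3.41 ± 0.06). All 6 histone bodies were above (HHT2 3.88 ± 0.06, HTB1 2.56 ± 0.10, HTB2 1.98 ± 0.06, HHO1 0.62 ± 0.06). The strain carries tagged H3 genes, and whether probes at HHT2 also read them could not be tested, here or for its promoter above. The ribosomal protein list, RPP1 included, had 70 above and 11 below of 109 (median 0.41, RPL9B 3.12 ± 0.07, RPL28 2.76 ± 0.07). Glucose-repressed carbon genes had 8 and 3 of 12 (HXT6 2.35 ± 0.09, SUC2 2.25 ± 0.13, JEN1 1.68 ± 0.06). Phosphate-starvation genes had 6 and 1 of 7 (PHO84 3.18 ± 0.10, PHO5 0.64 ± 0.10). RPL9B was measured on 6 arrays. Against other bodies these 7 lists stood higher by camera, with adjusted p = 1.88e-09 (pheromone), 1.71e-08 (glycolysis), 4.04e-05 (galactose), 0.00345 (histone), 4.77e-09 (ribosomal protein), 0.0341 (glucose-repressed) and 0.0475 (phosphate). For each the adjusted p = 0.226 with an estimated correlation. Camera did not account for the number of probes in a body, with which the ratio fell. All bodies with 1 to 2 probes had a median of 0.34, near that of the ribosomal protein list, and those with over 10 had -0.84. With arrays centred on coding bodies the glucose-repressed and phosphate lists did not pass (adjusted p = 0.0576 and 0.148). The phosphate list also did not pass with normexp (0.0631), with only probes well above background (0.054), without 120 min set 2 (0.0565) or without 150 min set 5 (0.0532), nor did the glucose-repressed list in scan 2 alone (0.0665).

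Bodies of 2 lists stood lower than other bodies by camera, G2/M and ribosome biogenesis genes. The number of probes was not accounted for here either, and all bodies with 6 to 10 probes had a median of -0.63, near both list medians. Of 10 G2/M genes, 9 were below and 0 above (median -0.67; HOF1 -0.99 ± 0.07, MYO1 -0.91 ± 0.06; camera adjusted p = 0.0499, and adjusted p = 0.292 with an estimated correlation). Of 19 ribosome biogenesis genes, 16 were below and 2 above (median -0.62; RPA190 -1.03 ± 0.06, UTP8 -0.94 ± 0.06, NHP2 1.03 ± 0.09, 6 arrays measured; adjusted p = 0.0386, and adjusted p = 0.226 with an estimated correlation). Centred on coding bodies, 7 ribosome biogenesis bodies lay above and 7 below (median -0.12), 1 G2/M body lay above and 6 below (median -0.18), and neither list passed camera (adjusted p = 0.0576 for both), nor did the G2/M list without either 90 min array, 120 min set 5 or 150 min set 5 (0.0565 to 0.0577), with normexp (0.0588) or with only probes well above background (0.0538). The ribosome biogenesis list did not pass without 120 min set 2 (0.0565), with only probes well above background (0.054) or in scan 2 alone (0.0765). Of 23 G1/S genes, 18 were below and 3 above (PCL1 -1.14 ± 0.10), of 33 proteasome genes 21 and 6 (RPN1 -0.93 ± 0.06; PRE7 2.10 ± 0.06), and of 19 meiosis genes 12 and 4 (SMK1 -1.05 ± 0.09; DIT2 1.60 ± 0.10). Medians of those 3 lists were -0.40, -0.41 and -0.41, and 0.10, 0.08 and 0.08 centred on coding bodies. The 4 bodies of the COS list, COS111 included (COS12 -0.84 ± 0.10), and the 3 silent cassette bodies were all below. Among the latter, HMLALPHA2 was at -1.24 ± 0.08 (6 arrays measured) and HMRA1 at -0.49 ± 0.08. General stress genes had 9 above and 4 below of 16 (GLK1 1.95 ± 0.07, XBP1 0.87 ± 0.06, CTT1 -0.76 ± 0.05). None of these 6 lists passed camera (adjusted p from 0.0967 to 0.579). No PAU body could be tested. Counts adjusted over the list alone were the same, except 4 rather than 3 glucose-repressed genes below.

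**Figure D1:**
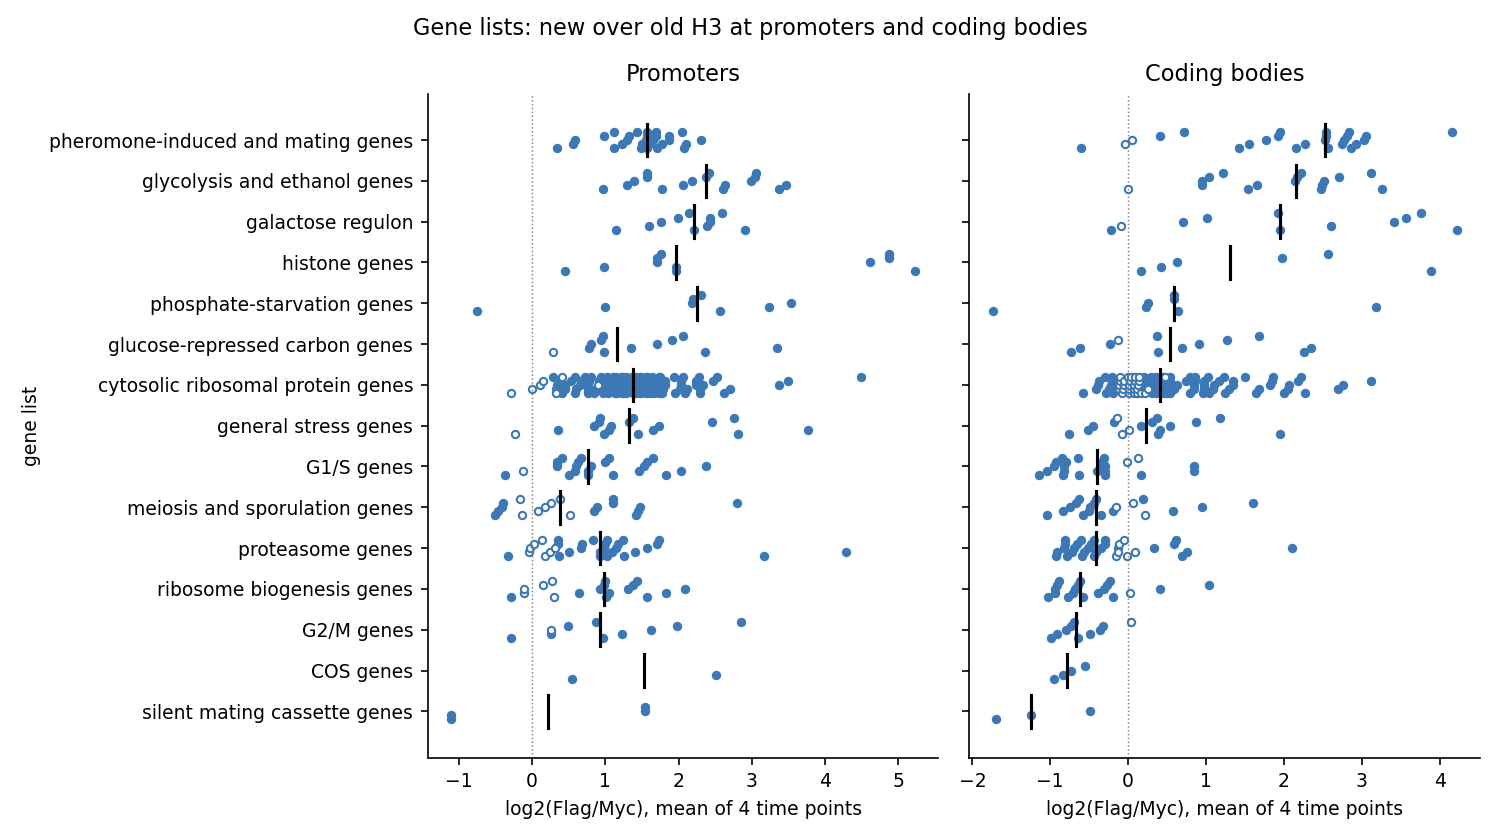
Each point is a gene of a fixed list, at its promoter (left) or coding body (right), as log2(Flag/Myc) averaged over the 4 time points; filled points passed limma at an adjusted p of 0.05, open points did not, and bars are list medians. Pheromone, glycolysis and galactose genes have body medians of 2.53, 2.15 and 1.95, while G2/M bodies have a median of -0.67.

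The GAL7, GAL10 and GAL1 genes on chromosome 2 show the contrast at a strongly induced locus. Probe means over arrays reached 4.77 within GAL10 (277198 to 277257, 7 arrays measured) and 3.70 within GAL1 (279987 to 280046, 6 arrays measured), and were lower, 2.17 and 2.10, at the 2 probes between these genes (278552 to 278825, measured on 7 and 6 arrays). They fell away to -0.49 inside the neighbouring FUR4 body (281938 to 281997) and were -0.58 at the far end of the region (273248 to 273307). FUR4, a uracil permease gene, has its promoter within the raised block, while its body was at -0.22 ± 0.07. The start of GAL10 is known only to lie between 277987 and 278448, so the first probe of its promoter value (278210 to 278269, mean 3.68) may lie within the gene.

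**Figure D2:**
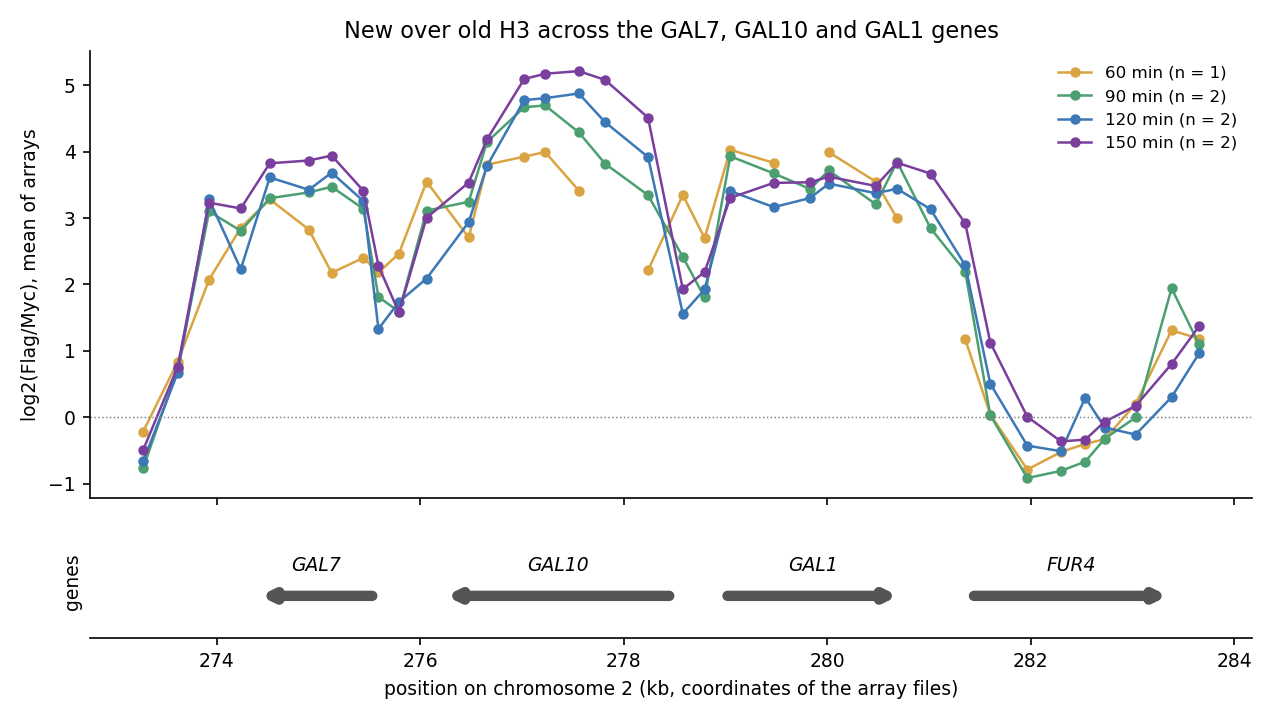
Points are probe values of log2(Flag/Myc), averaged over the arrays of each time (n = 1 at 60 min, n = 2 at the other times), against position on chromosome 2, with genes drawn as arrows in the direction of transcription up to the bracketed right ends. The 3 GAL genes stand above the array median at each time, and values return to about 0 within FUR4.

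Promoters were compared with the bodies of the same genes to ask where along genes new H3 enters. The promoter was higher in 4029 of 5122 genes and lower in 383 by limma, and the median difference per array was 1.09 ± 0.16 (SD, n = 7 arrays), ranging from 0.907 to 1.34. It was positive on 7 of 7 arrays (exact sign-flip permutation p = 0.0156, the smallest this design allows), at 1.06 in set 2 (3 arrays) and 1.12 in set 5 (4 arrays), and 0.976 within scan 2. The largest differences were at NRT1 (4.92 ± 0.16), SWI1 (a chromatin-remodelling subunit, 4.40 ± 0.13), SOK2 (a transcription factor, 4.16 ± 0.15) and LAF1 (4.09 ± 0.13). The body exceeded the promoter most at ICS3 (-2.84 ± 0.13), ARG80 (arginine metabolism, -2.46 ± 0.17), CWP2 (a cell wall protein, -2.42 ± 0.25) and ARP6 (a chromatin-remodelling subunit, -2.42 ± 0.17), the last 3 measured on 6 arrays. At GAL10 the order was also body above promoter, at 4.21 against 2.91.

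Intergenic probes had a higher ratio than coding bodies on every array. Relative to coding bodies, intergenic probes between divergent genes were higher by 1.53 ± 0.14 (SD, n = 7 arrays) and those between tandem genes by 1.51 ± 0.10. Those between convergent genes, where no promoter of the flanking genes lies, were higher by 0.74 ± 0.06. Intergenic classes were drawn from the kept genes alone, so other genes and their promoters may lie in them. Within bodies, the middle of 3 equal parts was lower by a difference of -0.28 ± 0.03, the 5' part was higher by 0.23 ± 0.04 and the 3' part by 0.12 ± 0.03. Probes near snoRNA genes exceeded bodies by 1.85 ± 0.17, near centromeres by 1.25 ± 0.18, near tRNA genes by 1.22 ± 0.15, near Ty elements and LTRs by 1.07 ± 0.12, and near chromosome ends by 0.20 ± 0.05. These classes differed from bodies with 1 sign on 7 of 7 arrays (exact sign-flip permutation, adjusted p = 0.0169 over 13 classes), as did the mitochondrial genome. Mitochondrial probes averaged 2.46 above bodies with a range from 0.675 to 6.12 between arrays, 0.88 in set 2 and 3.64 in set 5. Mitochondrial DNA carries no histones, so these values are not a share of new H3. They limit how far ratios of either set can be read as such a share, most of all in set 5, the 60 min array included. The silent loci HML and HMR, with 12 probes, differed from bodies by -0.01 ± 0.14 (exact p = 0.8125), below bodies on 5 and above on 2 of 7 arrays; without dye normalization they passed as lower. The rDNA had 3 probes, with array medians from 0.724 to 4.197 and no test.

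**Figure D3:**
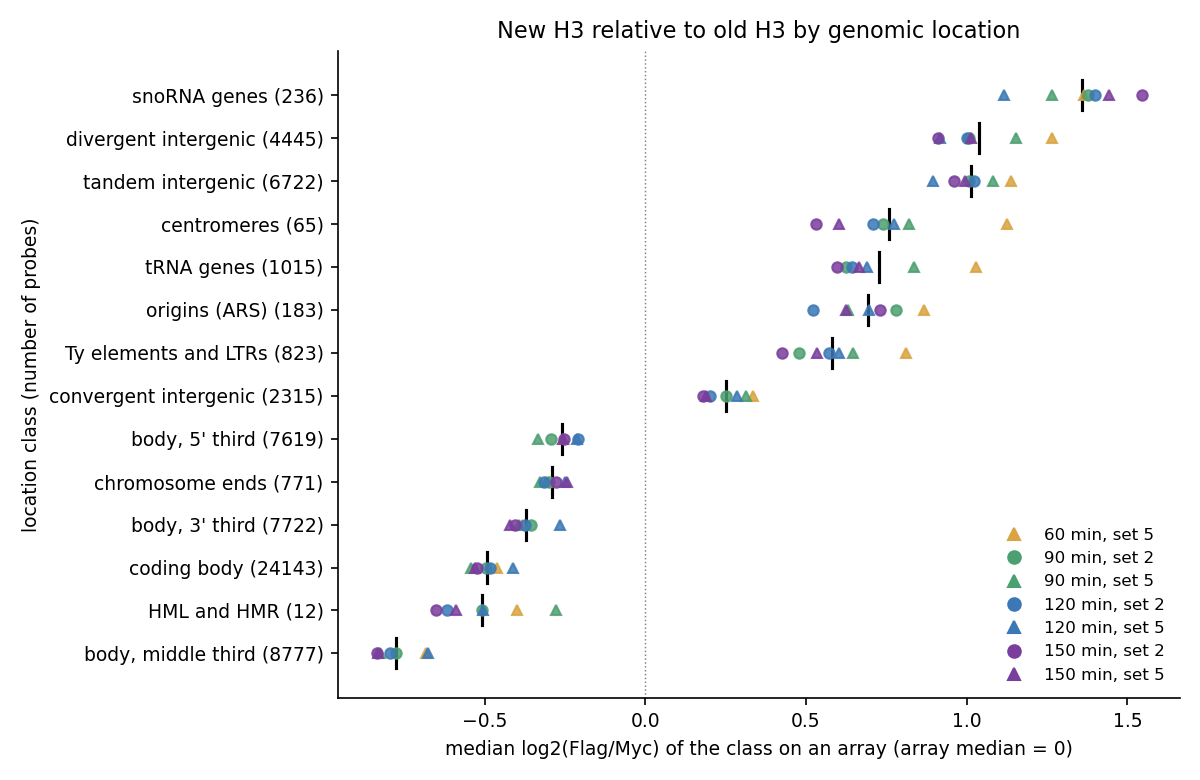
Each symbol is the median log2(Flag/Myc) of a location class on 1 array, coloured by minutes after galactose and shaped by set; black bars are means over the 7 arrays, and rDNA and mitochondrial probes are left out. Divergent and tandem intergenic probes average 1.04 and 1.01, and the middle of coding bodies -0.77.

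Between 90 and 150 min the ratio rose in the bodies of 300 genes and fell in 3 of 5221 (limma). The largest rises were in WSC2 (a cell wall sensor, 1.90 ± 0.14), CUP9 (a transcriptional repressor, 1.88 ± 0.17), QCR2 (a respiratory complex subunit, 1.86 ± 0.18), PGU1 (a polygalacturonase, 1.79 ± 0.15), ASN2 (asparagine synthesis, 1.73 ± 0.21) and GPD2 (glycerol synthesis, 1.63 ± 0.24), with limma adjusted p from 0.00477 to 0.0111. Of the 300 bodies 266 were above the array median in the mean over time, and their median went from 0.88 to 1.83. Their median rise was 0.96, and 299 of 299 measured in set 2 and 299 of 299 in set 5 rose. The bodies were chosen by a test on these same arrays, so this agreement is largely fixed by the choice. The bodies that fell were BOL1 (iron-sulfur cluster assembly, -0.85 ± 0.15, 6 arrays measured, adjusted p = 0.0252) and, named after their values were seen, YIL054W (-1.23 ± 0.17, 6 arrays measured) and YKL183C-A (-1.73 ± 0.19, 5 arrays measured), the latter pair not well above background on all arrays. In the fifth of bodies with the highest mean ratio the median change was 0.32 (0.38 in set 2, 0.27 in set 5), and in the lowest it was -0.02.

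The number of bodies called rests on few arrays. Without the 150 min set 2 array 9 bodies rose, without 150 min set 5 68 rose, and without 90 min set 5 73 rose and 2 fell. With scan as fixed terms 510 rose and 13 fell, with scan as a random block 477 and 4, and within scan 2 alone 478 and 13. Scan 2 holds 1 array at 90 min and 2 at 150 min, and with scan as fixed terms the change rests on the same arrays, so these are not separate tests. With normexp background correction 125 rose; for the 300 bodies the median change was 1.07 in that fit against 0.96, while the median SE was 0.22 against 0.16.

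By list, 6 of 16 glycolysis and ethanol bodies rose and 0 fell, 14 of them rising when adjusted over the list alone (median change 0.75; FBA1 0.84 ± 0.16). Of 25 pheromone and mating bodies 6 rose, 13 adjusted over the list alone (median 0.52), of 109 ribosomal protein bodies 7 rose, 10 adjusted over the list alone (median 0.33), and of 11 galactose-regulon bodies 1 rose, 8 adjusted over the list alone (median 0.54). Other bodies had a median change of 0.04 to 0.05. The fifth of all bodies with the highest mean ratio had 0.32, near that of the ribosomal protein list, and camera did not account for the mean ratio. By camera these 4 lists changed more than other genes, with adjusted p = 5.09e-08, 1.23e-05, 1.36e-07 and 0.00283 in that order, and adjusted p = 0.366, 0.366, 0.366 and 0.404 with an estimated correlation. Within scan 2 alone their median changes were 0.63, 0.60, 0.27 and 0.36, with camera adjusted p = 6.52e-07, 2.1e-06, 7.18e-07 and 0.0242, and with scan as fixed terms the adjusted p = 5.1e-07, 6.67e-07, 6.93e-07 and 0.027. The fixed terms leave the same arrays for the change, 1 of them at 90 min, so the paired values are 1 comparison and not 2. Within scan 2 the spread comes only from the difference between both 150 min arrays, 1 residual degree of freedom, so these p-values carry little weight. The other 11 lists with bodies tested did not pass (adjusted p from 0.0932 to 0.644), but the histone list passed upward without 120 min set 2 (0.0222), without 90 min set 5 (0.0364) and in scan 2 alone (0.00662), the phosphate list with normexp (0.0398), without 150 min set 2 (0.0453) and in scan 2 alone (0.0242), and the meiosis list passed downward without 150 min set 2 (0.0453). With an estimated correlation and all arrays their adjusted p = 0.474, 0.366 and 0.366. Single members that rose included PHO5 (acid phosphatase, 1.497 ± 0.25), XBP1 (1.03 ± 0.15), HXT6 (a hexose transporter, 1.01 ± 0.22), PRE7 (0.93 ± 0.16), HTB2 (0.74 ± 0.15), JEN1 (a lactate transporter, 0.74 ± 0.15) and IME2 (0.70 ± 0.14).

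**Figure D4:**
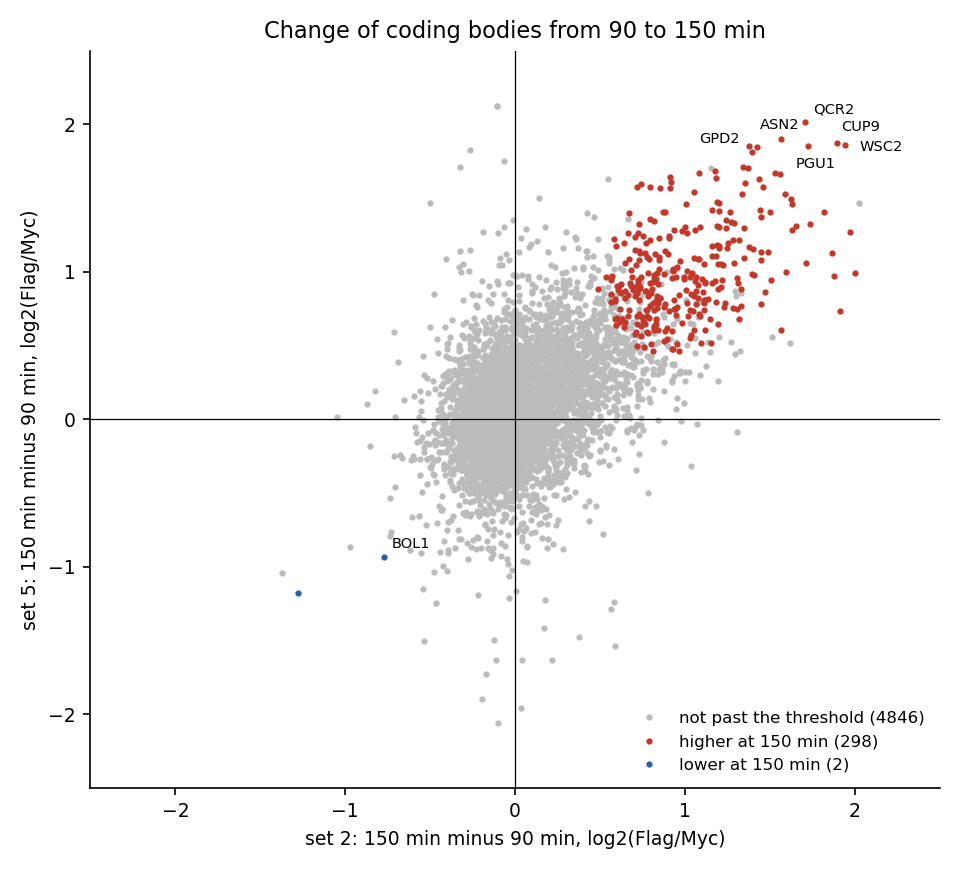
Each point is a coding body, with its change from 90 to 150 min in set 2 on the x axis and in set 5 on the y axis, in log2(Flag/Myc); red bodies were higher and blue bodies lower at 150 min by limma, and 2 bodies lie beyond the axes. The 298 red bodies measured in both sets lie above 0 on each axis, but they were chosen by a test on these same arrays.

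At promoters no time change passed. Limma called 0 of 5503 promoters, with 55 higher and 125 lower at an unadjusted p under 0.05, and 0 of 4301 promoters in the slope over all 4 times, with 177 higher and 508 lower at an unadjusted p under 0.05. By the test of 150 against 90 min, a 2-fold change was not detectable at promoters. In simulated data that test recovered 0% of changes of that size. The slope recovered 56.6% of 152 simulated changes of that size that ran linearly over the 4 times. Among promoters well above background with 1 direction in both sets, the largest changes with a standard gene symbol were 1.67 ± 0.33 at PRM10 (a pheromone-regulated gene), 1.54 ± 0.29 at ALG1 (glycosylation) and 1.53 ± 0.26 at RRT1 upward, and -2.16 ± 0.62 at OM14 (mitochondrial outer membrane), -1.44 ± 0.98 at RPL42A and -1.36 ± 0.65 at KIN82 (a kinase) downward, each with an adjusted p = 0.978 (RRT1 and RPL42A on 6 arrays). At the RPL42A promoter the change was 0.07 within scan 2. No promoter list passed (adjusted p from 0.151 to 0.996), and the 11 histone promoters had a median change of -0.66. Histone values shared by neighbouring genes count for both genes in this median and in the tests of the list. The histone list passed downward with only probes well above background (adjusted p = 0.00348), with a 250 bp window (0.0402) and without the 150 min set 2 array (0.00845), and the ribosomal protein list without 90 min set 2 (0.00223) or 150 min set 5 (0.00825); with all arrays the adjusted p = 0.924 with an estimated correlation for both. Single probes gave 0 calls among 37235, with 2470 higher and 687 lower at an unadjusted p under 0.05. Calls appeared, mostly upward, with only probes well above background (563 higher, 4 lower) and with scan as a random block (523 higher, 7 lower). Promoter slopes were called with only probes well above background (36 upward, 2 downward) and with a 250 bp window (12 upward, 1 downward). The promoter minus body difference, likewise, gave 0 calls among 5122 genes, with 30 higher and 376 lower at an unadjusted p under 0.05. Its array median was 1.34 at 60 min (n = 1), 1.17 ± 0.12 at 90 min, 1.02 ± 0.16 at 120 min and 0.96 ± 0.01 at 150 min (SD, n = 2 each).

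The spread of the ratio across probes was described by values alone. Its SD was 1.26 at 60 min (n = 1), 1.35 ± 0.11 at 90 min, 1.27 ± 0.03 at 120 min and 1.35 ± 0.04 at 150 min (SD, n = 2 each), and no test was run. Its interquartile range was 1.61, 1.81 ± 0.15, 1.73 ± 0.09 and 1.90 ± 0.01 in the same order. Regressed on the 90 min array of their own set, the later arrays had slopes of 1.03 and 1.03 in set 2 (120 and 150 min) and 0.74 and 0.815 in set 5.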

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

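Watson genes alone, and the use of scan, dim signal, background correction, spot intensity and set as tests of an explanation, were chosen after the results were seen, although the settings for dim signal, background, intensity and set were fixed beforehand. Tests of promoters of the same genes, the Myc signal and the middle of bodies were written down before their values were seen. The results listed next are those in which 150 min differed from 90 min by a test of that difference, or in which the ratio had a slope over time.

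Bodies that changed with time were 300 higher and 3 lower at 150 min, and by the slope over all 4 times 737 rising and 55 falling of 4924. The named bodies were WSC2 at 1.90, CUP9 at 1.88, QCR2 at 1.86, PGU1 at 1.79, ASN2 at 1.73, GPD2 at 1.63, PHO5 at 1.5, XBP1 at 1.03, HXT6 at 1.01, PRE7 at 0.93, FBA1 at 0.84, HTB2 at 0.74, JEN1 at 0.74, IME2 at 0.70 and BOL1 at -0.85. The lists were glycolysis and ethanol genes (median change 0.75), the galactose regulon (0.54), pheromone and mating genes (0.52) and ribosomal protein genes (0.33).

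The first pattern weighed is the rise of 300 bodies. Set 5 compared arrays of different scans and set 2 arrays of 1 scan, yet the 300 bodies with the largest change in set 5 had a median change of 0.77 in set 2, where all bodies had 0.01, which argues against scan as the whole source. With dim probes left out 363 bodies rose, and after loess on intensity the median change of the 300 bodies was 0.93 (quartiles 0.76 to 1.13), against 0.96 before it, which argues against weak signal and a drift with intensity as the whole source. Fewer passed after loess (207 rose) and after normexp (125 rose), because the change was smaller relative to its error: the median change and median SE were 0.93 and 0.17 with loess, 1.07 and 0.22 with normexp, and 0.96 and 0.16 before. That bodies gain new H3 later than promoters was not decided: the promoters of 291 of these genes had a median change of -0.14 against 0.97 for the bodies, but the bodies were chosen for having risen and the promoters were not, and base composition and cross-hybridisation stay open, as untested.

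The second pattern is the height of promoters over bodies. Promoters may look high where the Myc signal is low. Averaged over 10 bins of the Myc signal, intergenic promoter probes still exceeded body probes by 0.88 (range 0.63 to 1.17 over 7 arrays), against 1.55 unmatched. Matching thus removed part of the difference. Within a bin promoter probes may still have a lower Myc signal than body probes, so whether the Myc signal accounts for the rest was not decided. The smallest of the 10 bin differences, in whichever bin it fell, was negative on 3 arrays (-0.784, -0.075 and -0.031). Strand errors in the annotation do not produce it, since Watson genes alone gave 1.098. Weak Flag precipitation confined to set 5 does not, since set 2 alone gave 1.06. Set 2 is not free of DNA precipitated nonspecifically, because mitochondrial probes, whose DNA carries no histones, exceeded bodies by 0.88 there too. A nonspecific share in both sets is therefore not excluded. Loess on intensity lowered the median difference from 1.09 to 0.79. New H3 entering at promoters stays open as a hypothesis beside a remaining effect of the Myc signal. Nonspecific DNA, base composition and amplification bias were not tested and stay open too.

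The third pattern is the group of bodies above the array median. Bodies with few probes were more often in it: 811 of 1456 bodies with 1 to 2 probes, but 15 of 285 with over 10. A possible explanation is that DNA fragments from flanking regions are read at gene ends. In the 167 such bodies with at least 6 probes the middle of 3 equal parts had a median of 0.20, against 0.67 for the whole body, between the bounds set for and against it. Flanking DNA and new H3 within these 167 bodies, taken as a group, therefore cannot be told apart here, because the middle value falls between both bounds. Bodies with fewer probes were not tested, so the other bodies above the median are not covered.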

How the results depend on the processing

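Watson genes alone, scan as fixed terms, scan 2 alone and arrays without scan 3 were chosen after the data were seen; the other alternatives were planned. The number of bodies called in the mean ratio stayed within 1.5-fold, the location classes that passed numbered 12 or 13, and the median promoter minus body difference (0.79 to 1.12) stayed positive under every alternative run. The deposited table gave the same values and so tests nothing. Where no cause is named, the cause was not tested.

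With scan as a random block, which used fully measured features, probes called in the mean ratio numbered 16569 of 21666 tested, against 30702; probes changing with time 530 and bodies changing with time 481, against 0 and 303. With scan as fixed terms these were 161 and 523, within scan 2 alone 491 bodies, and without scan 3 75. With only well-measured probes 567 probes changed with time and 38 promoters had a slope, against 0 and 0; slopes were also called for 3 promoters with normexp, 8 with outlier spots kept and 13 with a 250 bp window. Normexp left 125 bodies changing with time and lowered the SD of the ratio from 1.32 to 1.16; loess lowered it to 1.25. Watson genes alone gave 2351 promoters and 2207 promoter minus body differences, from 2760 and 2583 tested. Lists passing with an estimated correlation were 0 for promoters, 0 for bodies and 0 for time, against 3, 9 and 4; by fry, which does not compare a list with other genes, 15 and 15 passed. Centred on coding bodies 5 body lists passed, and PAU23 (promoter, 0.011) and HMRA1 (body, 0.008) changed sign without passing.

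Leaving out 1 array at a time, where a lone array is taken to vary like the other groups, gave 20375 (without 120 min set 5) to 32620 probes and 9 (without 150 min set 2) to 338 bodies changing with time, 68 without 150 min set 5 and 75 without 90 min set 5. Promoter slopes ran from 0 to 1, and lists from 3 to 6 (promoters), 7 to 9 (bodies) and 4 to 7 (time). With set number as a block, 368 bodies changed with time (360 up, 8 down), the G2/M body list did not pass (adjusted p = 0.0525), and other counts of calls stayed within 1.5-fold; sets' differences correlated at -0.02, 0.12 and 0.22 between times, so the numbers were not read as a pairing. Within a single set the time change has no residual degrees of freedom and the classes cannot reach the threshold. Of the values of named genes under alternatives, 3742 kept direction and side of the threshold and 30 lost the call.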

Other observations

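The comparisons of classes with intergenic probes and of origins in this part were chosen after the results were seen, as were the relation of promoters to bodies and the split by number of probes.

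Classes near noncoding loci differed among themselves when set against intergenic probes of divergent and tandem genes, which averaged 1.02. The snoRNA, tRNA, centromere, Ty and origin classes took every probe within 500 bp, including any in coding bodies, which the reference leaves out. A value below the reference can therefore come from coding probes in the class, whose share was not measured. Probes near snoRNA genes were higher by 0.34 ± 0.16 (SD, n = 7 arrays) and on 7 of 7 arrays. Probes near tRNA genes differed by -0.30 ± 0.09, near centromeres by -0.26 ± 0.13, near Ty elements and LTRs by -0.44 ± 0.08 and near replication origins (183 probes at 54 origins) by -0.33 ± 0.12, each below on 7 of 7 arrays (exact sign-flip permutation p = 0.0156 for each of the 5 classes, not adjusted). Origins exceeded coding bodies by 1.19 ± 0.11 (SD, n = 7 arrays). Convergent intergenic probes differed from the same reference by -0.77 ± 0.07. Probes within 10 kb of chromosome ends (-1.31 ± 0.12) and at HML and HMR (-1.53 ± 0.10) lay near coding bodies (-1.51 ± 0.11).

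Centromere probes were highest at 60 min (1.13, n = 1), at 0.74 and 0.82 at 90 min, 0.71 and 0.77 at 120 min and 0.53 and 0.60 at 150 min (sets 2 and 5). Probes near tRNA genes were at 1.03 on the 60 min array, at 0.63, 0.64 and 0.60 in set 2 (90, 120 and 150 min) and at 0.84, 0.69 and 0.66 in set 5. No test of these changes was run. Mitochondrial probes, whose DNA carries no histones, were at 5.66 on the 60 min array and at 0.45, 0.53 and 0.15 in set 2 (90, 120 and 150 min) against 3.08, 1.45 and 2.44 in set 5.

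Across 5127 genes, which are not independent replicates, the mean ratio at the promoter correlated with that of the body (Pearson r 0.437, Spearman rho 0.374), whereas the changes from 90 to 150 min at promoter and body did so at a Spearman rho of 0.038. Body ratios fell with the number of probes per gene, from a median of 0.34 for 1 to 2 probes through -0.24 (3 to 5) and -0.63 (6 to 10) to -0.84 (over 10). Of the 300 bodies that rose with time, 84, 160, 52 and 4 came from these groups of 1456, 2255, 1225 and 285 genes.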
